A study of Mus musculus with 18 samples.

How the data were processed

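Cells of the mouse mammary gland were isolated by fluorescence-activated sorting, per the labels' protocols, as ER+ luminal, ER- luminal and basal cells at puberty, adulthood and mid pregnancy. The mice carried a tetracycline-controlled Cre and a fluorescent reporter (genotype ERrtTA/TetOCre/rosaYFP). The sorting gates and any doxycycline treatment are not given in the sources used here. Total RNA was purified with RNeasy micro kits and libraries were made with the Ovation Solo system, per the labels. Groups follow the sample titles. The cell type label of the puberty and pregnancy basal samples reads BC luminal cells, whereas that of the adult ones reads basal cells. Each of the 9 groups had 2 libraries.

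The authors deposited 1 table of whole-number signal values per gene and library. STAR, Picard, HTSeq and the mouse build GRCm38 are named per the submitters' processing notes. Versions, settings, the annotation release, the use of strand and the handling of duplicates are not given in the sources used here. Library totals lay between 19841695 and 19897395, and low values rose in library-specific steps. The deposited signal was therefore taken as read counts scaled to 20000000 and rounded up. Reads were recovered by inverting that rounding, which returned the deposited value exactly for 99.7% to 99.9% of non-zero values per library, where chance would give 12.1% to 57%. A stricter test, which asks for low values on whole steps with no allowance for rounding, was met by 3 libraries and missed by 15. Read depths, bounds and count-model results of these 15 libraries therefore rest on the inferred rounding. Reads of overlapping genes, antisense genes and close paralogs such as Krt6a and Krt6b or Ceacam1 and Ceacam2 cannot be told apart in such a table, so values of these genes are uncertain. Of 46868 rows, 790 repeated one of 179 gene IDs, and 46257 gene IDs were kept. Gene positions are from the GENCODE vM21 annotation of GRCm38, counted from 1, in which 45849 of these IDs were found. Of 137 genes that the naming rule and panel gave, 136 were among them, all but Mia2.

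Choices described in this paragraph were made before the data were examined. The test for normalized values was limma 3.58.1 in R 4.3.3 with trend and robust empirical Bayes on log2(value + 1). It covered 22315 genes with a value of at least 10 in at least 2 libraries, in 1 model with a mean per group and 9 residual degrees of freedom. Fold changes on this scale can understate the change of low genes above 0. Where a group is at 0 they can overstate it. The 1 added is below the value of 1 read, which was 1.75 to 8.25 per library. Calls are 2-sided at a Benjamini-Hochberg adjusted p under 0.05. Genes were named by a rule with a fixed panel of 21 genes. To these it added, per comparison, the 8 largest rises and falls among called genes whose compared libraries did not overlap and whose higher group mean lay above the median of tested genes. It further took up to 4 called members of each described list, and 5 genes per direction for each difference of pregnancy effects. Predicted, immunoglobulin, mitochondrial and ribosomal genes were passed over, and the text prints a part of the genes so chosen. The 31 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation or fry as alternatives. Lists share members: ER- luminal markers hold 6 milk protein genes, and basal markers share 8 genes with the contractile list, 2 with matrix genes and 1 with the WNT list. fry asks whether the genes of a list move 1 way on balance and does not compare them with other genes. Of 341 such tests, 133 passed at the preset correlation and 7 with an estimated one.

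Where both libraries of a group were at 0, the fold is a bound against 3 reads over the group. Bounds cover counting error only, since reads without molecular identifiers are not independent molecules. Alternatives were other pseudocounts, filters, scalings, priors and weights, the compared groups alone, replicate blocks, and each library left out. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads. Chosen after seeing the data were the comparisons of pregnancy with puberty, reads thinned to 2406221 per library, the removal of all adult or all pregnancy libraries, ER- luminal markers without milk protein genes, and the limit of 5-fold by which adult luminal groups are said to lie apart. Tables and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

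The tests were tried on simulated data drawn from the real means and depths. Counts followed a negative binomial model, the kind edgeR fits, with a common dispersion for all genes and libraries. Spread that differs between genes and library effects were left out, which favours edgeR. For ER+ against ER- luminal cells, limma recovered 78 of 100 genes changed 2-fold and 99 of 100 changed 4-fold among 21683 genes. For pregnancy against adult ER+ cells it recovered 15 and 87 of 100 among 21667 genes. There 62 of its 164 calls were unchanged genes, against 6 of 97 with edgeR, so the error of limma exceeded its nominal level. With no gene changed, 8.43% of p-values lay under 0.05 in this comparison at the real depths and 5.09% at equal depths. Among the other comparisons with adult luminal cells the share at the real depths was 7.75% for puberty in ER+ cells, 7.13% for pregnancy in ER- cells and 6.15% for puberty in ER- cells. For the differences of pregnancy effects it was 7.41% for ER- minus ER+, 6.29% for ER+ minus basal and 5.65% for ER- minus basal. limma was kept as chosen before the data were examined, and edgeR and thinned reads stand beside the comparisons with adult luminal cells. Beside the differences of pregnancy effects stand thinned reads, and for ER- minus ER+ also edgeR.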

Results

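RNA from 3 sorted populations of the mouse mammary gland was sequenced at 3 stages. The populations were estrogen receptor positive (ER+) luminal cells, which sense the ovarian hormones, estrogen receptor negative (ER-) luminal cells, which include the precursors of milk-producing cells, and basal cells, the contractile outer layer of the duct. The stages were puberty, adulthood and mid pregnancy. The resulting 9 groups held 2 libraries each, 18 in all, and values below are scaled read counts on a common library total of 20000000, as mean ± SD with n = 2. Log2 fold changes are of value + 1 and carry their standard error (±), and adjusted p-values are from limma with Benjamini-Hochberg adjustment over 22315 genes. The labels do not say that replicates were separate animals, so p-values measure only the spread between these samples, which may be technical.

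Depth was unequal between groups. The steps between low values put it at 7674870 to 11292204 reads in genes in the puberty libraries and 5280331 to 6363552 in pregnancy. Adult basal libraries had 7900552 and 4233226, adult ER- luminal libraries 2910657 and 3165232, and adult ER+ luminal libraries 2559365 and 2406221. The 4 adult luminal libraries also stood apart in content: 6 genes were at 60 or more in all 4 and at 0 in the other 14 libraries, and 6 genes were the reverse, whereas no other pair of groups had such a gene. Mitochondrial transcripts made up 5.9%, 4.73%, 7.07% and 5.69% of these 4 libraries, and at most 3.26% of the others. Spearman correlations across genes ran from 0.953 to 0.977 between replicates and from 0.84 to 0.964 between libraries of different groups.

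**Figure D1:**
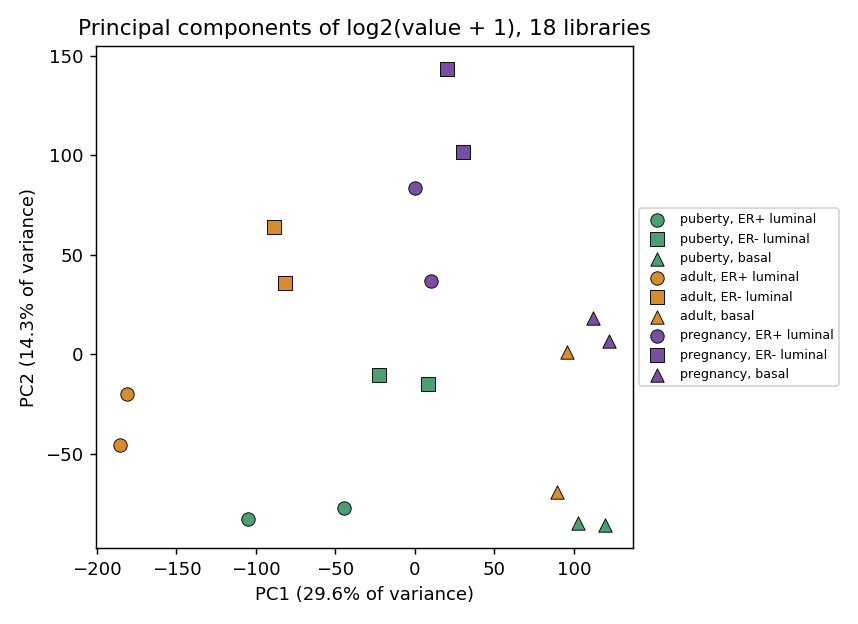
First and second principal components of log2(value + 1) for the 18 libraries, in arbitrary units, with 1 point per library, colour for stage and shape for cell type. PC1 holds 29.6% of the variance and PC2 14.3%.

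ER+ and ER- luminal cells were compared over the 3 stages to show what separates the hormone-sensing luminal population from the other. ER+ cells had more of the estrogen receptor gene Esr1 (log2 fold change 2.56 ± 0.36, adjusted p = 0.0004; chromosome 10, 4611593 to 5005614), with 11650 ± 624 in adult ER+ and 2810 ± 617 in adult ER- cells. The progesterone receptor gene Pgr (3.39 ± 0.39), the prolactin receptor gene Prlr (2.67 ± 0.43), the pioneer factor gene Foxa1 (3.09 ± 0.42) and the secreted ligands Areg (3.71 ± 0.46) and Wnt4 (2.80 ± 0.37) were higher as well. ER- cells had more Elf5, a transcription factor of the alveolar lineage (-2.77 ± 0.39, adjusted p = 0.000488; chromosome 2, 103411688 to 103450989), Kit, a receptor tyrosine kinase gene (-2.74 ± 0.29), and Aldh1a3, a retinaldehyde dehydrogenase gene (-2.58 ± 0.23). The largest rises by the naming rule were Upk3a (4.32 ± 0.31), Adarb2 (4.20 ± 0.56), Gipc2 (4.11 ± 0.71) and Ccbe1 (3.88 ± 0.54), and the largest falls were Stra6l (-4.31 ± 0.53), Klk10 (-3.71 ± 0.83), the glutamate transporter gene Slc1a2 (-3.58 ± 0.52) and Mgam (-3.52 ± 0.65). With a group at 0 set to its bound, Adarb2 was at 3.31 and Stra6l at -3.60.

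Among the fixed lists, ER+ luminal markers counted 13 of 14 higher and 0 lower, 14 and 0 adjusted over the list alone (camera adjusted p = 4.07e-14, adjusted p = 0.155 with an estimated correlation). ER- luminal markers counted 0 of 13 higher and 13 lower, 0 and 13 adjusted over the list alone (camera adjusted p = 1.47e-12, adjusted p = 0.155 with an estimated correlation), led by Trf (-3.23 ± 0.27), Lalba (-2.79 ± 0.44) and Elf5 (-2.77 ± 0.39). Over alternatives, adjusted p for all 13 ran from 1.61e-14 to 0.155. Of these, 6 are also milk protein genes. The other 7 counted 0 higher and 7 lower (camera adjusted p = 1.08e-07, adjusted p = 0.178 with an estimated correlation). Milk protein genes counted 0 of 16 higher and 12 lower, 0 and 13 adjusted over the list alone (camera adjusted p = 5.53e-09, adjusted p = 0.178 with an estimated correlation). Basement membrane and matrix genes counted 2 of 23 higher and 12 lower, 2 and 13 adjusted over the list alone (camera adjusted p = 0.00724, adjusted p = 0.558 with an estimated correlation). Markers of immune cells counted 0 of 19 higher and 7 lower, 0 and 12 adjusted over the list alone (camera adjusted p = 0.00308, adjusted p = 0.821 with an estimated correlation). In total 5691 genes differed, 2305 higher and 3386 lower in ER+ cells. Without the 6 pregnancy libraries, left out after seeing basal marker transcripts there, 5498 genes differed. Quantile normalization moved the median log2 fold change of all genes from -0.11 to 0.03 and the split to 3101 higher and 2729 lower.

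**Figure D2:**
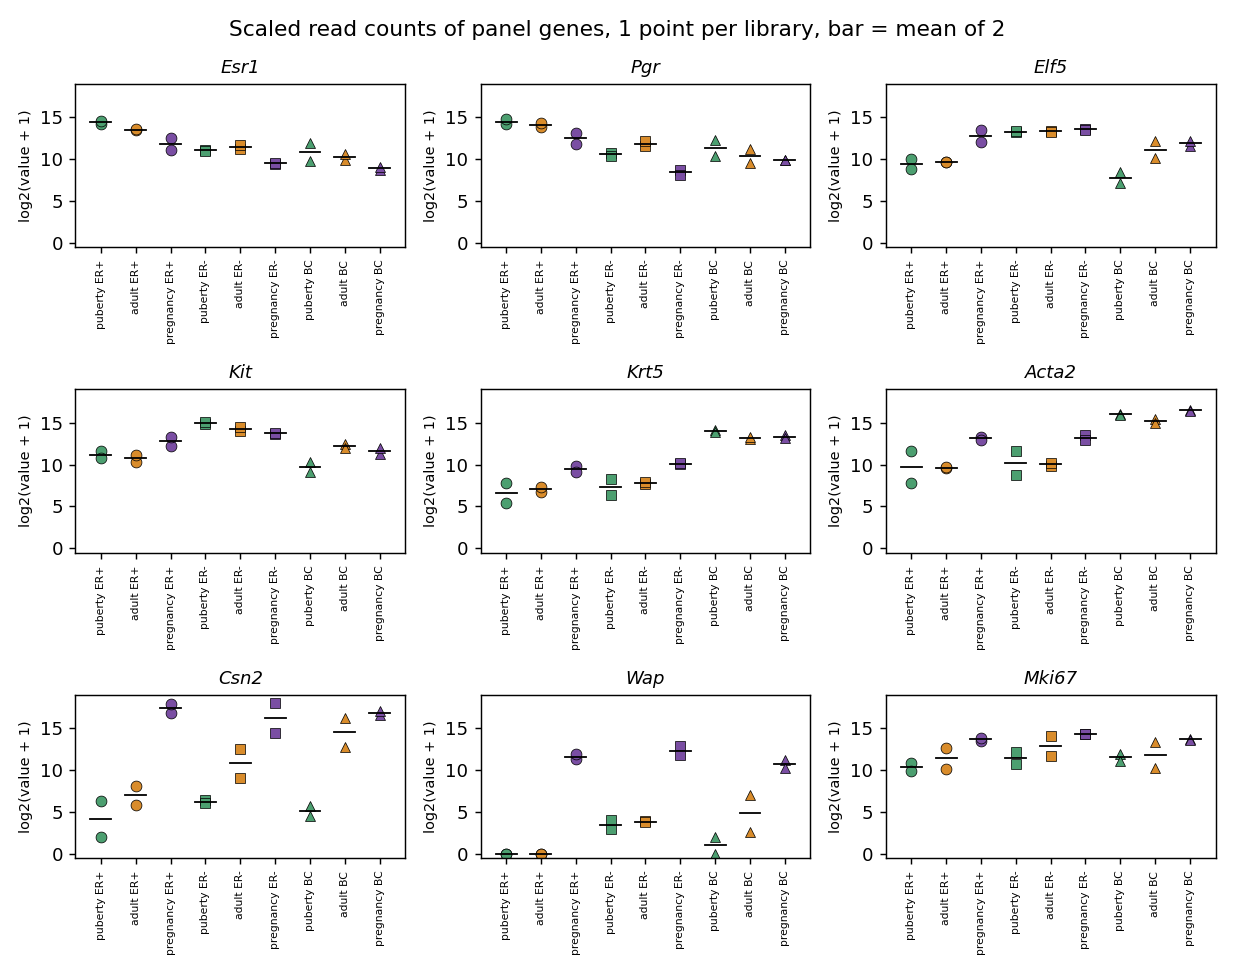
Log2(value + 1) of 9 panel genes in the 9 groups, where each point is 1 library and the bar is the mean of 2. Esr1 and Pgr lie highest in ER+ luminal cells, Krt5 and Acta2 in basal cells, and group means of Csn2 and Wap are highest in the 3 pregnancy groups.

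Basal cells were compared with both luminal populations over the 3 stages. Basal cells had more of the basal keratin genes Krt5 (5.43 ± 0.36, adjusted p = 6.5e-07; chromosome 15, 101707070 to 101712898) and Krt14 (5.33 ± 0.31), the transcription factor gene Trp63 (5.18 ± 0.36), smooth muscle actin Acta2 (4.90 ± 0.56) and the oxytocin receptor gene Oxtr (3.82 ± 0.29), which serves milk ejection. The luminal keratin genes Krt8 (-1.24 ± 0.14) and Krt18 (-1.85 ± 0.20) were lower in basal cells. The naming rule also gave Ccdc187 (6.20 ± 0.37), Nkain3 (6.04 ± 0.64), the WNT inhibitor gene Wif1 (5.88 ± 0.48), the WNT ligand gene Wnt10a (5.74 ± 0.49) and the ephrin receptor gene Ephb1 (5.68 ± 0.50) among rises, and Coro2a (-2.96 ± 0.23), the water channel gene Aqp5 (-2.69 ± 0.38), Tfcp2l1 (-2.48 ± 0.22) and Mlph (-2.44 ± 0.30) among falls. With a group at 0 set to its bound, Ccdc187 was at 5.58 and Wnt10a at 5.12.

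Basal markers counted 18 of 18 higher and 0 lower, 18 and 0 adjusted over the list alone (camera adjusted p = 1.98e-17, adjusted p = 0.139 with an estimated correlation). Contractile apparatus genes, 8 of which are also basal markers, counted 17 of 17 higher and 0 lower, 17 and 0 adjusted over the list alone (camera adjusted p = 1.18e-15, adjusted p = 0.139 with an estimated correlation). Matrix genes counted 21 of 23 higher and 0 lower, 22 and 0 adjusted over the list alone (camera adjusted p = 1.84e-18, adjusted p = 0.0115 with an estimated correlation). WNT pathway genes counted 18 of 26 higher and 2 lower, 19 and 3 adjusted over the list alone (camera adjusted p = 2.16e-08, adjusted p = 0.0474 with an estimated correlation), with Wnt10a (5.74 ± 0.49) and Wnt6 (4.54 ± 0.57). Other paracrine ligands counted 16 of 25 higher and 6 lower, 17 and 6 adjusted over the list alone (camera adjusted p = 0.000156, adjusted p = 0.0409 with an estimated correlation), with Cxcl14 (5.68 ± 0.30) and Bmp7 (4.31 ± 0.25). Pan-luminal markers counted 0 of 11 higher and 10 lower, 0 and 10 adjusted over the list alone (camera adjusted p = 3.31e-07, adjusted p = 0.207 with an estimated correlation). Cholesterol synthesis genes counted 0 of 22 higher and 10 lower, 2 and 12 adjusted over the list alone (camera adjusted p = 0.0104, adjusted p = 0.502 with an estimated correlation), and missed the threshold on thinned reads (adjusted p = 0.0579, range over alternatives 0.00252 to 0.502). Markers of cells outside the 3 populations were also higher in basal libraries. Those of endothelial cells counted 11 of 11 higher and 0 lower, 11 and 0 adjusted over the list alone (camera adjusted p = 7.79e-05, adjusted p = 0.422 with an estimated correlation). Those of fibroblasts counted 8 of 10 higher and 0 lower, 8 and 0 adjusted over the list alone (camera adjusted p = 4.29e-05, adjusted p = 0.268 with an estimated correlation). Those of pericytes counted 6 of 6 higher and 0 lower, 6 and 0 adjusted over the list alone (camera adjusted p = 0.000635, adjusted p = 0.24 with an estimated correlation). In total 9473 genes differed, 4669 higher and 4804 lower, and 8054 without the 6 adult libraries. Quantile normalization moved the median of all genes from -0.03 to -0.17 and gave 4162 higher and 6486 lower, and median-ratio factors moved that median to 0.07.

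The change from adulthood to mid pregnancy was measured within each population. In ER+ luminal cells, milk genes were among the largest rises. The casein gene Csn2 (chromosome 5, 87692624 to 87699630) was at 181820 ± 96030 in pregnancy and 169 ± 157 in adults (10.36 ± 1.83, adjusted p = 0.00437), and Csn1s2a rose likewise (11.81 ± 2.19). Glycam1 (at least 2338-fold higher), Wap (at least 264-fold higher), Lao1 (at least 246-fold higher), Gjb6 (at least 150-fold higher) and Pnmt (at least 91.2-fold higher) were at 0 in both adult libraries, the bound standing for 3 reads over the group. Glycam1 lost the call without either adult ER+ library or either pregnancy ER+ library. Falls included the alarmin gene Il33 (-7.98 ± 0.62), the synaptic adhesion gene Nrxn3 (-9.04 ± 1.44) and Sprr1a (-6.73 ± 1.23). The largest by the naming rule was Raver1 (-10.6 ± 0.79), as in ER- cells (-10.91 ± 0.79). Raver1 and Lipo1 set the adult luminal libraries apart, so batch and stage cannot be told apart in either comparison. Against puberty, within libraries free of the adult luminal differences, Csn2 rose by 13.22 ± 1.83, Il33 changed by -8.13 ± 0.62 and the RANK ligand gene Tnfsf11 rose by 11.70 ± 2.13 (adjusted p = 0.0047; chromosome 14, 78277445 to 78308043). Tnfsf11 was at 0 and 3 in the puberty ER+ libraries, a mean of 1.5. That lies below the bound of 3.37 used for this group at 0, so the fold of Tnfsf11 rests on few reads. By group means, both adult luminal groups had Glycam1 over 5 times lower than each of the other 7 groups. At puberty, though, Glycam1 was at 1617 and 0 in ER+, 353 and 4 in ER- and 495 and 5 in basal libraries. Csn2 in the pregnancy ER+ libraries was 113910 in replicate 1 and 249723 in replicate 2. In that order, mean log2 levels of ER- luminal markers were 11.13 and 12.10, and those of ER+ luminal markers 12.06 and 10.76. Esr1 was at 5666 and 2096 there, against 11208 and 12091 in adult ER+ and 2373 and 3246 in adult ER- libraries. Whether milk genes and ER- luminal markers rose within ER+ cells was not tested.

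In this comparison milk protein genes counted 15 of 16 higher and 0 lower, 16 and 0 adjusted over the list alone (camera adjusted p = 7.07e-12, adjusted p = 0.0816 with an estimated correlation). Against puberty they counted 12 of 16 higher and 1 lower, 14 and 1 adjusted over the list alone (camera adjusted p = 3.28e-11, adjusted p = 0.188 with an estimated correlation). Matrix genes counted 20 of 23 higher and 1 lower, 21 and 1 adjusted over the list alone (camera adjusted p = 7.78e-14, adjusted p = 0.0313 with an estimated correlation), with Tnc (4.87 ± 0.47), Fbln2 (3.95 ± 0.54) and Lama1 (3.75 ± 0.59). Lama1 was at 2888 and 2513 in pregnancy ER+ and 28406 and 26570 in pregnancy basal libraries. Fbln2 was at 2224 and 1205 against 19008 and 13222. Tnc differed from these, at 986 and 3155 against 844 and 1222. Whether matrix genes rose apart from basal transcripts in these libraries was not tested. Against puberty, matrix genes counted 11 of 23 higher and 1 lower, 13 and 1 adjusted over the list alone (camera adjusted p = 1.64e-06, adjusted p = 0.188 with an estimated correlation). Markers of cells outside the 3 populations moved with the matrix genes against adults. Fibroblast markers counted 7 of 10 higher and 0 lower, 9 and 0 adjusted over the list alone (camera adjusted p = 2.72e-05, adjusted p = 0.429 with an estimated correlation). Endothelial markers counted 4 of 11 higher and 0 lower, 7 and 0 adjusted over the list alone (camera adjusted p = 0.00159, adjusted p = 0.488 with an estimated correlation). Pericyte markers counted 2 of 6 higher and 0 lower, 5 and 0 adjusted over the list alone (camera adjusted p = 0.0244, adjusted p = 0.488 with an estimated correlation). Pericyte markers missed the threshold without adult ER+ replicate 2 (adjusted p = 0.0996) and without pregnancy ER+ replicate 1 (adjusted p = 0.0741), with a range over alternatives 0.0127 to 0.488. Of the other marker lists, those of erythroid cells counted 3 of 5 higher and 0 lower, 4 and 0 adjusted over the list alone (camera adjusted p = 0.0204, adjusted p = 0.488 with an estimated correlation). Erythroid markers missed the threshold without adult ER+ replicate 2 (adjusted p = 0.0751) and without pregnancy ER+ replicate 1 (adjusted p = 0.0852), with a range over alternatives 0.00899 to 0.488. Against puberty, of marker lists of other cell types, those of adipocytes counted 0 of 9 higher and 5 lower, 0 and 6 adjusted over the list alone (camera adjusted p = 8.89e-05, adjusted p = 0.437 with an estimated correlation). Lipid synthesis genes counted 13 of 24 higher and 0 lower, 17 and 1 adjusted over the list alone (camera adjusted p = 2.1e-05, adjusted p = 0.487 with an estimated correlation). ER- luminal markers counted 8 of 13 higher and 0 lower, 12 and 0 adjusted over the list alone (camera adjusted p = 6.03e-06, adjusted p = 0.429 with an estimated correlation). Over alternatives, adjusted p for all 13 ran from 3.39e-08 to 0.429. Of these, 6 are also milk protein genes. The other 7 counted 3 higher and 0 lower (camera adjusted p = 0.00612, adjusted p = 0.488 with an estimated correlation). Basal markers moved with the luminal lists and counted 13 of 18 higher and 1 lower, 17 and 1 adjusted over the list alone (camera adjusted p = 3.33e-07, adjusted p = 0.487 with an estimated correlation). Against puberty, basal markers counted 12 of 18 higher and 0 lower, 14 and 0 adjusted over the list alone (camera adjusted p = 1.03e-09, adjusted p = 0.488 with an estimated correlation). In total 3991 genes differed, 2865 higher and 1126 lower. Pregnancy and puberty differed in 2916, with 1391 without pregnancy ER+ replicate 2 and 1349 without puberty ER+ replicate 2. Counts against adult luminal libraries run high. In simulated data with no changed gene and these depths, limma called 15 to 35 genes per set in 5 sets, all of them higher. With 3000 changed genes 12.2% of its calls were unchanged genes, against 3.41% with edgeR, whose kind of model the simulation used. On the recovered reads edgeR called 3001 genes, thinning to the shallowest library left 2527, and the compared groups alone gave 0 with limma, with 5788 at an unadjusted p under 0.05. Removing adult ER+ replicate 2 left 2605 and removing pregnancy ER+ replicate 2 left 1825, and quantile normalization moved the median of all genes from 0.20 to -0.11 and gave 1896 higher and 1907 lower.

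In ER- luminal cells, pregnancy raised the fatty acid binding gene Fabp3 (10.28 ± 1.03, adjusted p = 5.76e-05), Wap (8.45 ± 1.06), Lao1 (9.15 ± 1.25) and Rgs8 (8.70 ± 1.14), while Glycam1 (at least 2467-fold higher) and Hephl1 (at least 35.3-fold higher) were at 0 in adults. Adult means were 3.5 for Fabp3 and Rgs8 and 7 for Lao1, below the bound of 9.81 used for this group at 0. The folds of these genes therefore rest on few adult reads and may be overstated. Lower in pregnancy were Nrxn3 (at least 77.8-fold lower), Il33 (-6.86 ± 0.62), Ccbe1 (-7.23 ± 0.93) and Abcc8 (-6.74 ± 1.35). Against puberty, Fabp3 changed by 8.40 ± 1.03, Wap by 8.81 ± 1.06 and Il33 by -5.82 ± 0.62, and the casein genes Csn2 (9.95 ± 1.83, adjusted p = 0.00738) and Csn1s2a (9.73 ± 2.19, adjusted p = 0.0172) rose. Csn1s2a lost the call against puberty without pregnancy ER- replicate 1 or either puberty ER- library. Csn2 lost the call against puberty without puberty ER- replicate 2. Mia2 was higher than in adults (7.62 ± 0.50) but not called against puberty (0.28 ± 0.50, adjusted p = 0.77). By group means, both adult luminal groups had Mia2, Cd36 and Glycam1 over 5 times lower than each of the other 7 groups. Single libraries bore this out for Mia2, at 7 to 149 in adult luminal libraries and at 1486 or more in all others. Glycam1 at puberty was at 353 and 4 in ER-, 1617 and 0 in ER+ and 495 and 5 in basal libraries. Cd36 in puberty ER+ replicate 2 (497) was close to adult ER- replicate 2 (458). Glycam1 and Cd36 thus do not clearly set the adult luminal libraries apart. Csn2 did not pass against adults (5.33 ± 1.83, adjusted p = 0.0829), with 253329 and 21279 in the 2 pregnancy libraries.

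Among lists in ER- cells, lipid synthesis genes counted 12 of 24 higher and 0 lower, 18 and 1 adjusted over the list alone (camera adjusted p = 4.43e-07, adjusted p = 0.499 with an estimated correlation), with Fabp3 (10.28 ± 1.03), Olah (5.64 ± 1.11) and Cd36 (4.54 ± 1.03). Against puberty, lipid synthesis genes counted 13 of 24 higher and 0 lower, 13 and 1 adjusted over the list alone (camera adjusted p = 1.18e-06, adjusted p = 0.393 with an estimated correlation). Milk protein genes counted 4 of 16 higher and 1 lower, 6 and 2 adjusted over the list alone, with a median log2 fold change of 1.19, and did not pass as a list (camera adjusted p = 0.0792, adjusted p = 0.611 with an estimated correlation). Against adults the list passed the threshold with a pseudocount of 5 (adjusted p = 0.0333) and without pregnancy ER- replicate 2 (adjusted p = 0.00814), with a range over alternatives 0.00814 to 0.627. Against puberty they counted 5 of 16 higher and 2 lower, 9 and 3 adjusted over the list alone, with a median of 1.14, and did not pass either (camera adjusted p = 0.0897, adjusted p = 0.571 with an estimated correlation). Against puberty the list passed the threshold with a pseudocount of 5 (adjusted p = 0.0391), without pregnancy ER- replicate 2 (adjusted p = 0.0101) and without puberty ER- replicate 2 (adjusted p = 0.0216), with a range over alternatives 0.0101 to 0.571. Oxidative phosphorylation genes counted 9 of 22 higher and 0 lower, 13 and 0 adjusted over the list alone (camera adjusted p = 7.5e-06, adjusted p = 0.499 with an estimated correlation). ER+ luminal markers counted 1 of 14 higher and 7 lower, 1 and 9 adjusted over the list alone (camera adjusted p = 2.73e-05, adjusted p = 0.499 with an estimated correlation). Basal markers in ER- cells counted 9 of 18 higher and 1 lower, 15 and 1 adjusted over the list alone (camera adjusted p = 1.46e-06, adjusted p = 0.499 with an estimated correlation). Endothelial markers there counted 5 of 11 higher and 0 lower, 9 and 0 adjusted over the list alone (camera adjusted p = 1.48e-05, adjusted p = 0.499 with an estimated correlation). Of the other marker lists, those of pericytes counted 1 of 6 higher and 0 lower, 3 and 0 adjusted over the list alone (camera adjusted p = 0.034, adjusted p = 0.499 with an estimated correlation). Those of immune cells counted 2 of 19 higher and 0 lower, 3 and 0 adjusted over the list alone (camera adjusted p = 0.0384, adjusted p = 0.611 with an estimated correlation). Pericyte markers missed the threshold with fry (adjusted p = 0.0615), without adult ER- replicate 1 (adjusted p = 0.0731) and without pregnancy ER- replicate 1 (adjusted p = 0.239), with a range over alternatives 0.0108 to 0.499. Immune cell markers missed the threshold with fry (adjusted p = 0.142), on thinned reads (adjusted p = 0.0648), without adult ER- replicate 1 (adjusted p = 0.248) and without pregnancy ER- replicate 1 (adjusted p = 0.189), with a range over alternatives 0.0197 to 0.611. Of such lists against puberty, those of immune cells counted 6 of 19 higher and 0 lower, 7 and 0 adjusted over the list alone (camera adjusted p = 0.000529, adjusted p = 0.393 with an estimated correlation). Those of adipocytes counted 0 of 9 higher and 6 lower, 0 and 6 adjusted over the list alone (camera adjusted p = 4.59e-05, adjusted p = 0.393 with an estimated correlation). In total 3213 genes differed, 1983 higher and 1230 lower. Pregnancy and puberty differed in 3307, with 1134 without pregnancy ER- replicate 2, 1942 without puberty ER- replicate 1 and 853 without puberty ER- replicate 2. Abcc8 and Olah lost the call without adult ER- replicate 2 or pregnancy ER- replicate 2. Cd36 lost the call without either adult ER- library or pregnancy ER- replicate 2. Glycam1 lost the call without either adult ER- library or either pregnancy ER- library. Simulated data with 3000 changed genes gave 10.3% unchanged genes among limma's calls and 3.21% among edgeR's, and on the recovered reads edgeR called 2534, or 1881 by limma after thinning. Without pregnancy ER- replicate 2, which had a lower share of its reads in the most abundant genes (2.08% in the top 10 against 9.48% in replicate 1), 775 genes differed, and without adult ER- replicate 2 924. Array weights, which were equal for both libraries of a group, gave 1616 and the compared groups alone 1363. Median-ratio factors split the calls 1596 higher and 1681 lower. Quantile normalization, which moved the median of all genes from 0.09 to -0.03, gave 1529 higher and 1803 lower.

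In basal cells, pregnancy raised Rgs8 (6.67 ± 1.14, adjusted p = 0.00355), Wap (5.89 ± 1.06), Fabp3 (5.39 ± 1.03), the insulin-like growth factor binding gene Igfbp2 (4.95 ± 0.74) and the macrophage genes F13a1 (4.54 ± 1.12) and Siglec1 (4.34 ± 0.90). The choline transporter gene Slc5a7 (-7.35 ± 1.34), Krt6a (-4.63 ± 1.00) and Il24 (-4.44 ± 1.16) were lower. Matrix genes counted 8 of 23 higher and 0 lower, 15 and 0 adjusted over the list alone (camera adjusted p = 1.3e-09, adjusted p = 0.0995 with an estimated correlation). Contractile genes counted 6 of 17 higher and 0 lower, 6 and 0 adjusted over the list alone (camera adjusted p = 3.38e-06, adjusted p = 0.631 with an estimated correlation). Fibroblast markers counted 4 of 10 higher and 0 lower, 6 and 0 adjusted over the list alone (camera adjusted p = 9.46e-08, adjusted p = 0.384 with an estimated correlation). Interferon response genes counted 0 of 21 higher and 5 lower, 0 and 8 adjusted over the list alone (camera adjusted p = 0.00119, adjusted p = 0.631 with an estimated correlation). Of the other marker lists, those of erythroid cells counted 1 of 5 higher and 0 lower, 5 and 0 adjusted over the list alone (camera adjusted p = 0.000668, adjusted p = 0.384 with an estimated correlation). Those of immune cells counted 2 of 19 higher and 0 lower, 4 and 0 adjusted over the list alone (camera adjusted p = 0.0325, adjusted p = 0.696 with an estimated correlation). Immune cell markers missed the threshold with fry (adjusted p = 0.428), with a pseudocount of 5 (adjusted p = 0.0516), without adult basal replicate 1 (adjusted p = 0.249) and without pregnancy basal replicate 2 (adjusted p = 0.277), with a range over alternatives 0.00131 to 0.696. Against adults, milk protein genes in basal cells counted 1 of 16 higher and 0 lower, 1 and 0 adjusted over the list alone, with a median of 0.37, and did not pass as a list (camera adjusted p = 0.359, adjusted p = 0.793 with an estimated correlation). Their mean log2 level was 11.60 and 10.10 in the adult and 11.60 and 11.97 in the pregnancy basal libraries. Milk genes rose against puberty and counted 10 of 16 higher and 0 lower, 13 and 1 adjusted over the list alone (camera adjusted p = 1.4e-19, adjusted p = 0.046 with an estimated correlation), with Csn1s2a (11.93 ± 2.19), Csn2 (11.68 ± 1.83) and Csn1s1 (11.43 ± 1.85). ER- luminal markers moved with them in basal cells and counted 4 of 13 higher and 0 lower, 8 and 1 adjusted over the list alone (camera adjusted p = 2.96e-07, adjusted p = 0.247 with an estimated correlation). Over alternatives, adjusted p for all 13 ran from 2.27e-10 to 0.247. Of these, 6 are also milk protein genes. The other 7 counted 2 higher and 0 lower (camera adjusted p = 0.00102, adjusted p = 0.431 with an estimated correlation). Among markers of other cell types against puberty, those of fibroblasts counted 0 of 10 higher and 0 lower, 0 and 0 adjusted over the list alone (camera adjusted p = 0.00307, adjusted p = 0.488 with an estimated correlation). Those of endothelial cells counted 0 of 11 higher and 0 lower, 0 and 0 adjusted over the list alone (camera adjusted p = 0.0162, adjusted p = 0.714 with an estimated correlation). Those of immune cells counted 0 of 19 higher and 0 lower, 0 and 0 adjusted over the list alone (camera adjusted p = 0.00756, adjusted p = 0.615 with an estimated correlation). Those of adipocytes counted 0 of 9 higher and 5 lower, 0 and 7 adjusted over the list alone (camera adjusted p = 4.03e-12, adjusted p = 0.046 with an estimated correlation). Fibroblast markers missed the threshold with fry (adjusted p = 0.399), with a range over alternatives 0.00317 to 0.488. Endothelial markers missed the threshold with fry (adjusted p = 0.566), without pregnancy basal replicate 2 (adjusted p = 0.0919) and without puberty basal replicate 2 (adjusted p = 0.193), with a range over alternatives 0.00501 to 0.714. Immune cell markers missed the threshold with fry (adjusted p = 0.566) and without pregnancy basal replicate 2 (adjusted p = 0.313), and turned direction without puberty basal replicate 1 (adjusted p = 0.703), with a range over alternatives 1.76e-10 to 0.703. In total 1620 genes differed from adults, 651 higher and 969 lower, and 461 from puberty, the latter 100 without pregnancy basal replicate 1, 75 without pregnancy basal replicate 2, 158 without puberty basal replicate 1 and 240 without puberty basal replicate 2. F13a1 and Il24 lost the call without either adult basal library or either pregnancy basal library. Fabp3 and Krt6a lost the call without adult basal replicate 2 or either pregnancy basal library. Rgs8 lost the call without adult basal replicate 2. Siglec1 lost the call without pregnancy basal replicate 2. Slc5a7 lost the call without adult basal replicate 2 or pregnancy basal replicate 2. Wap lost the call without pregnancy basal replicate 1. Csn1s1, Csn1s2a and Csn2 lost the call against puberty without either pregnancy basal library or either puberty basal library. Interferon response genes missed the threshold without pregnancy basal replicate 1 (adjusted p = 0.0652, range over alternatives 5.06e-06 to 0.631) and with fry (adjusted p = 0.106), as contractile genes did with fry (adjusted p = 0.127, range over alternatives 4.19e-07 to 0.631). Single libraries decide the size of this count, which was 2539 without adult basal replicate 1, 193 without adult basal replicate 2, 251 without pregnancy basal replicate 1 and 337 without replicate 2. TMM factors gave 1194 higher and 978 lower, and DESeq2 on the recovered reads called 3006.

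Puberty was compared with adulthood in the same way. Genes of adipocytes were higher at puberty in libraries of all 3 populations. Mean log2 levels of adipocyte markers at puberty were 9.39 and 7.33 in ER+, 9.99 and 8.17 in ER- and 10.22 and 11.14 in basal libraries. In adults these levels were 3.68 and 3.43, 4.53 and 4.88, and 5.63 and 5.68. At puberty replicate 1 was higher in both luminal populations. Whether these transcripts came from the sorted cells was not tested. In ER+ luminal cells Cyp2e1 (at least 158-fold higher) and Retn (at least 16.2-fold higher) were at 0 in adults, and the adipsin gene Cfd (9.12 ± 1.38, adjusted p = 0.00271) and the lipid droplet gene Cidec (6.79 ± 1.27) rose. Cidec lost the call without puberty ER+ replicate 1. Adipocyte markers counted 7 of 9 higher and 0 lower, 7 and 0 adjusted over the list alone in ER+ cells (camera adjusted p = 4.11e-07, adjusted p = 0.0978 with an estimated correlation). In ER- cells they counted 7 of 9 higher and 0 lower, 7 and 0 adjusted over the list alone (camera adjusted p = 1.33e-07, adjusted p = 0.217 with an estimated correlation). In basal cells they counted 6 of 9 higher and 0 lower, 8 and 0 adjusted over the list alone (camera adjusted p = 2.17e-08, adjusted p = 0.112 with an estimated correlation). In ER+ cells other paracrine ligands counted 9 of 25 higher and 0 lower, 13 and 0 adjusted over the list alone (camera adjusted p = 2.28e-06, adjusted p = 0.0153 with an estimated correlation). Matrix genes counted 10 of 23 higher and 0 lower, 14 and 0 adjusted over the list alone (camera adjusted p = 5.12e-08, adjusted p = 0.0562 with an estimated correlation). Markers of other cell types moved with these lists. Those of fibroblasts counted 3 of 10 higher and 0 lower, 8 and 0 adjusted over the list alone (camera adjusted p = 5.4e-06, adjusted p = 0.399 with an estimated correlation). Those of endothelial cells counted 2 of 11 higher and 0 lower, 10 and 0 adjusted over the list alone (camera adjusted p = 1.32e-06, adjusted p = 0.479 with an estimated correlation). Those of pericytes counted 2 of 6 higher and 0 lower, 3 and 0 adjusted over the list alone (camera adjusted p = 0.0136, adjusted p = 0.487 with an estimated correlation). Pericyte markers missed the threshold with fry (adjusted p = 0.0527), without adult ER+ replicate 2 (adjusted p = 0.0997) and without puberty ER+ replicate 1 (adjusted p = 0.203), with a range over alternatives 9.93e-05 to 0.487. Among the remaining marker lists, those of erythroid cells counted 1 of 5 higher and 0 lower, 3 and 0 adjusted over the list alone (camera adjusted p = 0.017, adjusted p = 0.487 with an estimated correlation). Erythroid markers missed the threshold without adult ER+ replicate 2 (adjusted p = 0.1) and without puberty ER+ replicate 1 (adjusted p = 0.102), with a range over alternatives 0.0109 to 0.487. In total 1278 genes differed in ER+ cells, 1005 higher and 273 lower. Raver1 and Lipo1, among the largest falls by the naming rule, belong to the genes that set the 4 adult luminal libraries apart, and batch and stage cannot be told apart for this comparison in luminal cells. Simulated data with 3000 changed genes gave 10.9% unchanged genes among the calls. On the real reads edgeR called 995, thinning left 744, array weights 752, removing puberty ER+ replicate 1 718, and the compared groups alone 0 with limma, with 3488 at an unadjusted p under 0.05. Quantile normalization, which moved the median of all genes from 0.07 to -0.07, gave 652 higher and 356 lower.

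In ER- luminal cells at puberty, Cyp2e1 (9.17 ± 1.37, adjusted p = 0.00184), the gluconeogenic enzyme gene Pck1 (7.68 ± 1.59), Mia2 (7.34 ± 0.50) and Ceacam2 (6.23 ± 1.12) were higher than in adults, and the WNT agonist gene Rspo1 (-6.78 ± 1.18) and Pde2a (-5.06 ± 1.06) were lower. Both adult luminal groups had Mia2 and Ceacam2 over 5 times lower and Pde2a over 5 times higher than each of the other 7 groups. Interferon response genes counted 12 of 21 higher and 0 lower, 17 and 0 adjusted over the list alone (camera adjusted p = 9.69e-15, adjusted p = 0.217 with an estimated correlation), with Ifit3 (5.47 ± 0.93), Ifit1 (3.29 ± 0.45) and Isg15 (3.13 ± 0.58). Endothelial markers counted 1 of 11 higher and 0 lower, 5 and 0 adjusted over the list alone (camera adjusted p = 7.88e-07, adjusted p = 0.404 with an estimated correlation). Endothelial markers missed the threshold with fry (adjusted p = 0.0584), with a range over alternatives 2.12e-13 to 0.404. Of the other marker lists, those of fibroblasts counted 0 of 10 higher and 0 lower, 0 and 0 adjusted over the list alone (camera adjusted p = 0.0495, adjusted p = 0.763 with an estimated correlation). Those of pericytes counted 1 of 6 higher and 0 lower, 2 and 0 adjusted over the list alone (camera adjusted p = 0.0107, adjusted p = 0.489 with an estimated correlation). Fibroblast markers missed the threshold with fry (adjusted p = 0.41) and without adult ER- replicate 1 (adjusted p = 0.209), and turned direction without puberty ER- replicate 2 (adjusted p = 0.721), with a range over alternatives 1.56e-07 to 0.763. Pericyte markers missed the threshold with fry (adjusted p = 0.121) and without puberty ER- replicate 1 (adjusted p = 0.196), with a range over alternatives 8.25e-05 to 0.489. In total 817 genes differed, 541 higher and 276 lower. Ceacam2 and Pde2a lost the call without adult ER- replicate 1 or either puberty ER- library. Ifit3 lost the call without puberty ER- replicate 2. Isg15 lost the call without adult ER- replicate 2 or puberty ER- replicate 2. Pck1 lost the call without adult ER- replicate 2 or puberty ER- replicate 1. Rspo1 lost the call without adult ER- replicate 1 or puberty ER- replicate 2. Simulated data with 3000 changed genes gave 7.37% unchanged genes among the calls, edgeR called 888 on the real reads, DESeq2 1315, thinning left 511 and the compared groups alone 16. The count was 386 without adult ER- replicate 1, 330 without puberty ER- replicate 1 and 329 without replicate 2.

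In basal cells at puberty, Cyp2e1 (10.41 ± 1.37, adjusted p = 0.000699), Cidec (8.13 ± 1.27), Cfd (8.01 ± 1.38) and the adiponectin gene Adipoq (7.13 ± 1.13) were higher. Casein genes were lower than in adults, with Csn1s1 at -9.86 ± 1.85 and Csn2 at -9.39 ± 1.83, as was the mucin gene Muc4 (-8.06 ± 0.61). Both caseins lost the call without replicate 1 of adult or puberty basal cells. Csn2 was at 77881 and 6854 in adult basal, 6053 and 546 in adult ER- libraries. Whether basal cells made it was not tested. Milk protein genes counted 0 of 16 higher and 11 lower, 0 and 12 adjusted over the list alone (camera adjusted p = 2.85e-10, adjusted p = 0.112 with an estimated correlation). ER- luminal markers in basal cells counted 0 of 13 higher and 7 lower, 0 and 8 adjusted over the list alone (camera adjusted p = 1.32e-06, adjusted p = 0.277 with an estimated correlation). Over alternatives, adjusted p for all 13 ran from 1.24e-08 to 0.277. Of these, 6 are also milk protein genes. The other 7 counted 0 higher and 4 lower (camera adjusted p = 0.000893, adjusted p = 0.352 with an estimated correlation). Pan-luminal markers there counted 0 of 11 higher and 5 lower, 0 and 7 adjusted over the list alone (camera adjusted p = 1.51e-05, adjusted p = 0.342 with an estimated correlation). Of the other marker lists, those of fibroblasts counted 1 of 10 higher and 0 lower, 4 and 0 adjusted over the list alone (camera adjusted p = 0.000464, adjusted p = 0.442 with an estimated correlation). Those of erythroid cells counted 1 of 5 higher and 0 lower, 4 and 0 adjusted over the list alone (camera adjusted p = 0.00617, adjusted p = 0.352 with an estimated correlation). Fibroblast markers missed the threshold with fry (adjusted p = 0.112), with a range over alternatives 0.000157 to 0.442. Erythroid markers missed the threshold without adult basal replicate 1 or puberty basal replicate 2, with a range over alternatives 0.000234 to 0.352. WNT pathway genes counted 7 of 26 higher and 0 lower, 8 and 2 adjusted over the list alone (camera adjusted p = 0.000822, adjusted p = 0.277 with an estimated correlation) and missed the threshold without adult basal replicate 1 (adjusted p = 0.0518, range over alternatives 1.24e-05 to 0.277). In total 2172 genes differed, 1023 higher and 1149 lower, and edgeR called 3388. The count was 789 without adult basal replicate 2, 378 without puberty basal replicate 1 and 1318 without replicate 2, the compared groups alone gave 600, and TMM factors split the calls 1573 higher and 1165 lower.

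**Figure D3:**
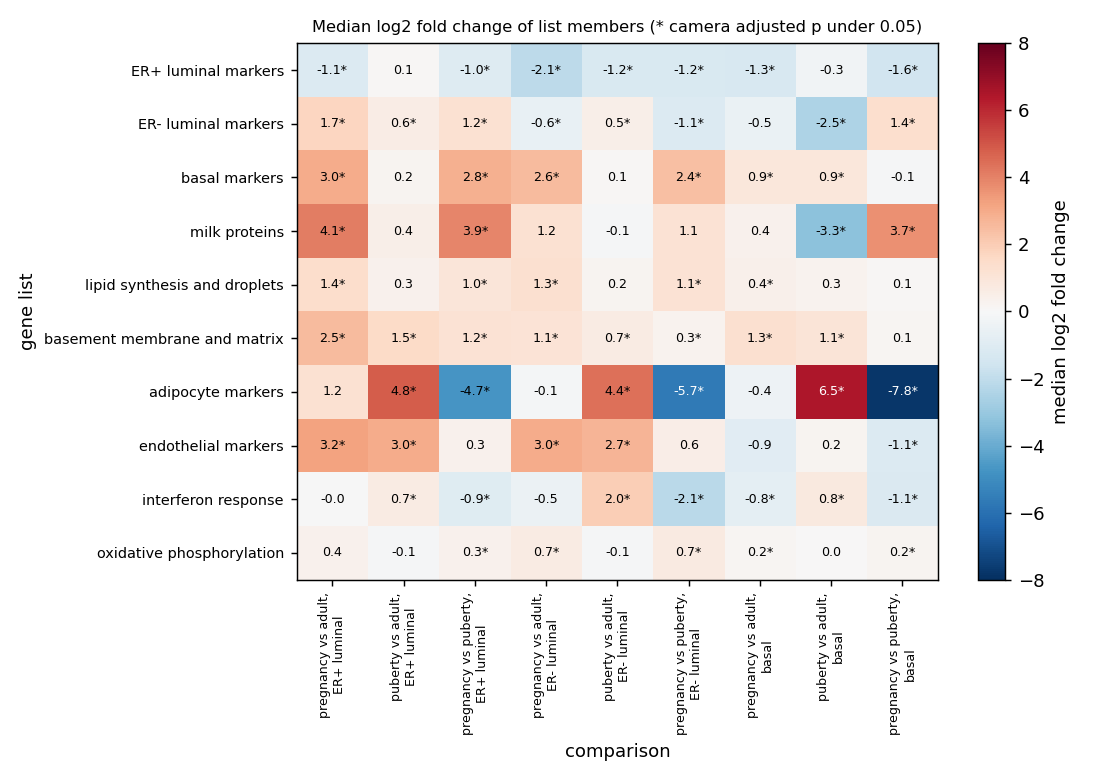
Median log2 fold change of the members of 10 gene lists (rows) in the 9 comparisons between stages (columns), with a star where camera's adjusted p at the preset correlation was under 0.05. Adipocyte markers are higher at puberty in every cell type, and milk proteins are higher in pregnancy than at puberty in ER+ luminal and basal cells. With an estimated correlation, camera's adjusted p for adipocyte markers at puberty against adults was 0.0978 (ER+), 0.217 (ER-) and 0.112 (basal). For milk proteins in pregnancy against puberty it was 0.188 (ER+) and 0.046 (basal).

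Whether the change from adulthood to pregnancy differed between populations was tested directly. It differed between ER- and ER+ luminal cells for 462 genes, and 412 of them changed less or fell more in ER- cells, among them Aldh1a3 (-3.13 ± 0.58, adjusted p = 0.0132), Lgi2 (at most -4.50) and Podn (at most -3.44), whose adult ER+ libraries were at 0 and set to the bound of 3 reads over the group. Of the 462 genes, 121 had a group at 0, so that the fitted difference rests on the pseudocount, as for 396 of the 1887 and 101 of the 441 below. Simulated data with no changed gene and these depths gave 0 to 2 calls per set for this difference, with 7.41% of p-values under 0.05. Aldh1a3 lost the call without adult ER- replicate 2 or pregnancy ER- replicate 2. Of marker lists of other cell types, those of fibroblasts counted 0 of 10 higher and 0 lower, 0 and 3 adjusted over the list alone (camera adjusted p = 2.47e-05, adjusted p = 0.351 with an estimated correlation). Fibroblast markers missed the threshold with fry (adjusted p = 0.0792), with a range over alternatives 2.24e-07 to 0.351. Between ER+ luminal and basal cells it differed for 1887 genes, 1476 higher and 411 lower, with the milk protein gene Lalba (4.62 ± 1.08) and Kit (2.57 ± 0.70) higher and Il33 (-8.12 ± 0.87) lower in ER+ cells. Kit lost the call without either adult basal library, either adult ER- library, adult ER+ replicate 1, either pregnancy basal library, either pregnancy ER- library, pregnancy ER+ replicate 2 or either puberty ER- library. Lalba lost the call without either adult basal library, adult ER+ replicate 1, either pregnancy basal library or pregnancy ER+ replicate 2. The fitted difference of Wap (5.71 ± 1.49) rests on adult ER+ libraries at 0, and was at least 2.01 with that group at its bound, so its call rests on the pseudocount. Of marker lists of other cell types in that difference, those of endothelial cells counted 2 of 11 higher and 0 lower, 7 and 0 adjusted over the list alone (camera adjusted p = 0.00026, adjusted p = 0.744 with an estimated correlation). Endothelial markers missed the threshold with fry (adjusted p = 0.0544), with a range over alternatives 2.27e-05 to 0.744. Between ER- luminal and basal cells it differed for 441 genes, 292 higher and 149 lower, with the chemokine scavenger gene Ackr1 (7.61 ± 1.00) and Il33 (-6.99 ± 0.87). Endothelial markers moved the same way as Ackr1 and counted 1 of 11 higher and 0 lower, 9 and 0 adjusted over the list alone (camera adjusted p = 1.26e-07, adjusted p = 0.624 with an estimated correlation). Endothelial markers missed the threshold with fry (adjusted p = 0.0984), with a range over alternatives 8.33e-09 to 0.624. Among the remaining marker lists there, those of fibroblasts counted 0 of 10 higher and 0 lower, 0 and 4 adjusted over the list alone (camera adjusted p = 5.16e-06, adjusted p = 0.624 with an estimated correlation). Fibroblast markers missed the threshold with fry (adjusted p = 0.291), with a range over alternatives 6.79e-08 to 0.624. Both adult luminal groups had Ackr1 over 5 times lower than each of the other 7 groups. Ackr1 was at 7 ± 0 in adult and 212 ± 33.9 in pregnancy ER- cells, and at 1049 ± 62.2 and 143 ± 27.6 in basal cells. The F test of the whole interaction called 1911 genes. The count for ER- against ER+ was 203 without adult ER- replicate 2, 209 without pregnancy ER- replicate 2 and 300 without pregnancy ER+ replicate 2. For ER- against basal it was 214 without adult basal replicate 2, 282 without adult ER- replicate 2, 108 without pregnancy basal replicate 1, 136 without pregnancy basal replicate 2 and 125 without pregnancy ER- replicate 2. For ER+ against basal it was 1134 without adult basal replicate 2, 870 without pregnancy basal replicate 1, 967 without pregnancy basal replicate 2 and 1029 without pregnancy ER+ replicate 2. For the interaction it was 1122 without pregnancy basal replicate 1, 1163 without pregnancy basal replicate 2 and 1248 without puberty basal replicate 1. Both luminal-to-basal differences set the adult luminal libraries against basal ones, so batch and cell type cannot be told apart there. Thinning left 267, 239 and 1074 genes in the differences of ER- from ER+, ER- from basal and ER+ from basal cells. Median-ratio factors gave 233 higher and 258 lower for ER- against basal, TMM factors 244 higher and 216 lower and quantile normalization 283 higher and 309 lower, and for ER+ against basal median-ratio factors gave 1432 higher and 744 lower and quantile normalization 1027 higher and 866 lower.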

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

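The tests of the 3 patterns below were chosen after the results were seen, whereas the tests of differences between cell types and the splits of single libraries were chosen before, and the splits of whole groups after. The change from adulthood to pregnancy differed between cell types by a test of the difference itself. It differed for 462 genes for ER- against ER+ luminal cells, 441 for ER- luminal against basal cells, 1887 for ER+ luminal against basal cells and 1911 for the whole interaction. The count for ER- against ER+ was 203 without adult ER- replicate 2, 209 without pregnancy ER- replicate 2 and 300 without pregnancy ER+ replicate 2. The other counts also fell without single libraries, as given above. Pregnancy ER+ replicate 2 lay nearer to ER- libraries in Elf5 and Kit than replicate 1 did. Whether ER- cells in that library gave the ER- against ER+ differences was not tested.

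Between ER- and ER+ luminal cells the median log2 difference was -2.79 for ER- luminal markers (adjusted p range over alternatives 1.7e-16 to 0.116) and -3.02 (-2.70 with groups at 0 set to their bound) for milk proteins. These lists share 6 genes. The other 7 ER- luminal markers had a median of -2.51 (camera adjusted p = 1.82e-06). Mean log2 levels of milk proteins were 10.34 and 9.98 in adult ER- and 6.83 and 6.77 in adult ER+ libraries. In pregnancy they were 13.27 and 12.35 in ER- and 12.09 and 13.15 in ER+ libraries. Milk protein levels thus lay apart in adults and overlapped in pregnancy. Pregnancy ER- replicate 2, where abundant transcripts were lower, had Csn2 at 21279, against 253329 in replicate 1. The median difference was -1.28 for matrix genes and -1.60 (-1.10 with groups at 0 set to their bound) for mesenchymal transition genes. Fibroblast markers moved with these (-2.52, camera adjusted p = 2.47e-05, adjusted p = 0.351 with an estimated correlation, adjusted p = 0.0792 by fry). Hormone receptors (-0.59) missed the threshold without adult ER- replicate 2 or adult ER+ replicate 1 (adjusted p from 0.133 to 0.186, range over alternatives 0.00547 to 0.351), and EGF family genes (-0.56) without adult ER+ replicate 1 or pregnancy ER+ replicate 1 (adjusted p from 0.0572 to 0.0831, range over alternatives 0.000643 to 0.284). Aldh1a3 differed by -3.13 ± 0.58. Aldh1a3 lost the call without adult ER- replicate 2 or pregnancy ER- replicate 2. Between ER+ luminal and basal cells the median was 4.61 (3.53 with groups at 0 set to their bound) for milk proteins, 2.19 for ER- luminal markers (adjusted p range over alternatives 4.6e-08 to 0.551), 1.95 for the 7 outside the milk list (camera adjusted p = 0.0122), and 1.10 for matrix genes. Milk solute transport (0.99) missed the threshold without adult basal replicate 1, either adult ER+ library, pregnancy basal replicate 1 or pregnancy ER+ replicate 2 (adjusted p from 0.0536 to 0.135, range over alternatives 0.00774 to 0.744). Wap differed by 5.71 ± 1.49 as fitted and by at least 2.01 with the adult ER+ group, which was at 0, set to its bound, so that its call rests on the pseudocount, Lalba by 4.62 ± 1.08 and Kit by 2.57 ± 0.70. Kit and Lalba lost the call without single libraries, as given above. Wap lost the call without adult basal replicate 1, either adult ER+ library, either pregnancy basal library or either pregnancy ER+ library. None of these list calls held with an estimated correlation, where the lowest adjusted p was 0.116.

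In replicate 2 of pregnancy ER- luminal cells, abundant transcripts were lower than in replicate 1. Less milk gene expression alone is argued against by 13 of the 20 most abundant other genes, which were lower by more than 1 on the log2 scale, against 0 in each of the other 8 replicate pairs. That test was added after a first one, the median of 294 abundant genes outside the milk list (-0.04), decided nothing because they went both ways. Reads capped per position, as duplicate removal would do, stay open as a candidate explanation, since across the 300 most abundant genes the log ratio rose with transcript length (Spearman correlation 0.74, against -0.44 to 0.363 in the other pairs). Genes are not independent replicates here, and no other biological explanation was tested.

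Only in the 4 adult luminal libraries were 12 genes present or missing, against 0 for other pairs of groups. Lower depth is argued against by 6 of them, at 60 or more in all 4 and 0 in the other 14 libraries. They include Raver1, Lipo1 and, named after its values were seen, Snord16a. Among missing ones are further IDs of Sgsm3, Umad1, Ltbp4, Map2k7 and Tead2. Another gene annotation or library batch stays open as a candidate explanation. Labels do not separate it from the adult stage in luminal cells, open and untested.

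Basal marker transcripts were higher in pregnancy luminal libraries than at the other stages, although sorting would remove basal cells. The 50 most abundant of 298 genes over 16-fold higher in basal cells were chosen at the other stages, limiting their share there. Their median was 12.3% and 11.8% of the basal level in pregnancy ER- and 11.9% and 8.21% in ER+ libraries. At other stages it was 0.686% to 4.04%. The adult luminal reference is argued against by 8 of 18 basal markers called higher against puberty in ER- cells and 12 in ER+ cells. Basal cells or their RNA stay open, as does a rise within luminal cells, untested. Ratios under 0.25 of the median cannot decide, at 0% of genes and 0% to 6% at other stages. Quartiles lay closer by ratio in pregnancy (6.7% and 12.1% in ER+ replicate 2) than elsewhere (1.3% and 2.7% in adult ER+ replicate 2). Acta2 was at 9679 ± 2471 in pregnancy ER-, 9049 ± 1805 in ER+ and 91646 ± 3041 in basal cells.

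With libraries split as single units, the real split gave the most called genes for both comparisons between cell types. With the 2 classes alone in the model, ER+ against ER- luminal cells gave 1842 genes, the highest of the other splits 915, and 1 of 100 splits, the real one, was as large. Basal against luminal cells gave 5363 genes, the highest other split 1800, and 1 of 100 was as large. Since these splits ignore that libraries come as replicate pairs, which may be technical, they cannot exclude chance. With whole groups split, ER+ against ER- luminal cells had 10 splits, too few for a share under 0.05, with 1842 genes in the real split, 1108 in the highest other and 1 split as large. For basal against luminal cells 1 of 84 splits of whole groups, the real one, was as large, with 5363 genes against 4033 in the highest other. That share is under 0.05, which argues against an arbitrary choice of whole groups there.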

How the results depend on the processing

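Comparisons of pregnancy with puberty, thinned reads, ER- luminal markers without milk protein genes and the removal of all adult or all pregnancy libraries were chosen after seeing the data. Of the counts of calls, 436 alternative values stayed within 1.5 times of the chosen fit and 82 did not, 39 of these on leaving out a library. The cause was not tested, and counts both fell and rose with fewer libraries. Quantile normalization gave 2503 for pregnancy against adult basal. limma with no trend or robust prior gave 933 for pregnancy against adult basal, 1385 for puberty against adult basal, 273 for the ER- minus basal difference and 244 for pregnancy against puberty basal. limma with no trend or robust prior also gave 1062 for the interaction. Array weights gave 1616 for pregnancy against adult ER-, 752 for puberty against adult ER+, 204 for the ER- minus ER+ difference and 262 for the ER- minus basal difference. Array weights also gave 1844 for pregnancy against puberty basal. The compared groups alone gave 0 for pregnancy against adult ER+, 1363 for pregnancy against adult ER-, 850 for pregnancy against adult basal and 0 for puberty against adult ER+. The compared groups alone also gave 16 for puberty against adult ER-, 600 for puberty against adult basal, 286 for the ER- minus ER+ difference and 678 for the ER- minus basal difference. The compared groups alone also gave 1431 for pregnancy against puberty ER+ and 1509 for pregnancy against puberty basal. edgeR on recovered reads gave 3388 for puberty against adult basal and 297 for the ER- minus ER+ difference. DESeq2 on recovered reads gave 3006 for pregnancy against adult basal, 1315 for puberty against adult ER-, 3756 for puberty against adult basal and 866 for the ER- minus basal difference. DESeq2 on recovered reads also gave 1321 for pregnancy against puberty basal and 3646 for the interaction. Thinned reads gave 2527 for pregnancy against adult ER+, 1881 for pregnancy against adult ER-, 1056 for pregnancy against adult basal and 744 for puberty against adult ER+. Thinned reads also gave 511 for puberty against adult ER-, 267 for the ER- minus ER+ difference, 239 for the ER- minus basal difference and 1074 for the ER+ minus basal difference. An estimated correlation between genes gave 7 for the list tests. The 2 counts of 0 with limma stand beside 5788 genes in pregnancy and 3488 at puberty at an unadjusted p under 0.05, and 3001 and 995 calls of edgeR. The compared groups alone were not fitted separately for basal against luminal cells or the interaction, which use all libraries. Leaving out each library gave 4373 to 5817 for ER+ against ER-, 7921 to 9662 for basal against luminal, 1825 to 4162 for pregnancy against adult ER+ and 775 to 3510 for pregnancy against adult ER-. The same ranges were 193 to 2539 for pregnancy against adult basal, 718 to 1397 for puberty against adult ER+, 329 to 910 for puberty against adult ER- and 378 to 2316 for puberty against adult basal. They were 203 to 619 for the ER- minus ER+ difference, 108 to 512 for the ER- minus basal difference, 870 to 2068 for the ER+ minus basal difference and 1349 to 3203 for pregnancy against puberty ER+. Further ranges were 853 to 3713 for pregnancy against puberty ER-, 75 to 616 for pregnancy against puberty basal, 1122 to 2043 for the interaction and 126 to 140 for the list tests. A group left with 1 library is assumed to vary like the others. Under other settings named genes kept their side of the threshold 1698 times, lost the call 69 times and gained it 3 times. On leaving out a library they kept it 2011 times and lost the call 95 times, and no sign changed in either. Lists in the text lost the call 100 times under other settings and 32 times on leaving out a library, and gained it 2 and 4 times. Immune cell markers for pregnancy against puberty in basal cells turned direction without puberty basal replicate 1 (adjusted p = 0.703), within a range of 1.76e-10 to 0.703 over libraries left out. Fibroblast markers for puberty against adult in ER- cells turned direction without puberty ER- replicate 2 (adjusted p = 0.721), within a range of 1.56e-07 to 0.721 over libraries left out. Endothelial markers for pregnancy against puberty in ER+ cells turned direction without puberty ER+ replicate 1 (adjusted p = 0.108), within a range of 0.000423 to 0.754 over libraries left out. Counts moved by thinned reads, given above, depend on depth.

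Same-numbered samples of a stage deviated together with correlations of 0.06 to 0.09 in adults, 0.02 to 0.08 in pregnancy and 0.06 to 0.27 at puberty. Of these 9 correlations 1 lay over 0.1, which all would need to pass for the numbers to be taken to pair samples. In adults, though, cell cycle genes had a higher mean log2 level in replicate 1 than in replicate 2 of each population (8.99 against 7.28 in ER+, 9.86 against 7.81 in ER- and 9.55 against 7.02 in basal cells), and so did oxidative phosphorylation genes (10.76 against 10.28, 10.40 against 9.89 and 10.54 against 10.01). A factor shared by same-numbered adult samples is therefore not excluded. The replicate block moved the ER- minus ER+ difference to 862, the ER- minus basal difference to 883 and the interaction to 2962. As a random effect it gave 723 and 685 for these differences.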

Other observations

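Comparisons of pregnancy with puberty were chosen after seeing the data. Interferon response genes in ER- luminal cells counted 1 of 21 higher and 16 lower, 2 and 16 adjusted over the list alone in pregnancy against puberty (camera adjusted p = 8.17e-12, adjusted p = 0.393 with an estimated correlation). Class II antigen presentation genes counted 5 of 7 higher and 0 lower, 6 and 0 adjusted over the list alone in that comparison (camera adjusted p = 0.000207, adjusted p = 0.393 with an estimated correlation). Immune cell markers rose there too, from mean log2 levels of 5.93 and 5.17 at puberty to 6.99 and 7.25 in pregnancy. Whether class II genes rose within ER- cells was not tested. At puberty against adulthood class II genes in ER- cells counted 0 of 7 higher and 2 lower, 0 and 5 adjusted over the list alone (camera adjusted p = 6.28e-05, adjusted p = 0.397 with an estimated correlation), with an adjusted p of 0.0545 by fry (range over alternatives 1.83e-06 to 0.397).

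Endothelial markers in ER+ luminal cells, in pregnancy against puberty, counted 0 of 11 higher and 0 lower, 0 and 0 adjusted over the list alone (camera adjusted p = 0.451, adjusted p = 0.865 with an estimated correlation). There the median was 0.34, the mean -0.03 and the direction of camera down. Without puberty ER+ replicate 1 that direction was up (adjusted p = 0.108), and without replicate 2 it was down and past the threshold (adjusted p = 0.000423, range over alternatives 0.000423 to 0.865).

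The proliferation gene Mki67 differed between adult replicates 1 and 2 of all 3 populations. It was at 6322 and 1163 in ER+ luminal, 16523 and 3409 in ER- luminal and 10126 and 1252 in basal cells.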
